A study of Mus musculus with 6 samples.

How the data were processed

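RNA was extracted with Trizol from isolated islets of C57BL6 mice and sequenced, per the labels' protocols, with 3 samples from mice on normal chow and 3 from mice on a high-fat diet, numbered here within each diet in deposit order. The table was made with Partek, per the submitters' processing notes. Its version, the aligner, the genome build, the way reads were assigned to genes and the library preparation are not given in the sources used here. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical.

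The deposited table held 1 column per sample and 48321 gene names. Its header gave no unit. Every column had a lowest value of exactly 1, and in 5 of the 6 columns the values less 1 piled up on multiples of 1 step per column, the same for all genes. The deposited values were therefore read as CPM plus 1, made by the authors, with 1 subtracted here. The CPM of a column summed to between 674482 and 963615. The step gave the worth of 1 read and from it the implied totals, from 18.8 to 35.1 M reads. At 3 reads the floor of a library lay between 0.0856 and 0.16 CPM, which covers counting error only. Of the values worth up to 20 reads, 64.6% to 70% were whole reads within 0.1. Whole reads were not recovered for this reason, and the count model fixed before the data were examined was replaced by limma on log2 values.

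The column of chow replicate 2 equalled the mean of the columns of chow replicates 1 and 3 in 48321 of 48321 gene names, and no other column was the mean of 2 others. It was the column with no step of its own. It was left out of the fits, which used 5 libraries (2 chow and 3 high-fat), and the fit with all 6 columns was kept as an alternative. Gene names, which were in capitals, were matched to mouse symbols for 46369 names, and 27 names had been turned into dates and were left as they stood. Gene classes, transcript lengths, GC content and shared 31-base words came from GENCODE M21, which may differ from the annotation the authors used, and no coordinates are given.

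Differences between diets were tested with limma 3.58.1 in R 4.3.3, on log2(CPM + 1) with a trend in the variance prior, for the 16939 genes with a mean of at least 0.5 CPM over the 5 libraries. The plan written before the data were examined named log2(value + 1) for normalized values. Since the deposited values already held the added 1, log2(CPM + 1) was used, and the literal form, 2 added to the CPM, was run as an alternative. Fold changes on this scale understate the change of low genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 of 35 lists with at least 5 tested members. None of the lists was called with an estimated correlation. The self-contained test fry called 5 lists in 1 direction and 30 for changes in either direction. Shares of the summed CPM were compared by exact two-sided permutation tests.

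The samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, and the fit on 5 libraries was chosen after. The rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 1 CPM over all 6 columns and no overlap between the diets, leaving out predicted genes, clone names and pseudogenes. It added the 4 members with the smallest p of each list that was called or had at least 3 members past the threshold, 17 genes of insulin signalling and islet hormones, and 6 genes as checks of the samples. Genes named outside it (members past the threshold of lists with fewer than 3, and the genes of the closing part) were chosen after their values were seen. Some of the genes the rule named are not reported here.

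The fit was tested on simulated data with the means and residual spread of the 16939 genes in 2 chow and 3 high-fat libraries. Of 100 genes changed by a log2 fold of 1, 64% were called in the right direction, and of 100 changed by 2, 95%, with 8 false calls among 167. The changed genes were drawn from those with a mean log2(CPM + 1) above 2, so the recovery does not cover lower genes. In 20 simulations a list moved by 0.5 was called 20 times, and 4 of 640 tests of unmoved lists were called. The simulated genes varied independently, whereas the estimated correlations of the lists called in the data ran from 0.31 to 0.99. The simulated libraries also held no shared difference such as acinar content. The simulations therefore cannot give the rate of false gene or list calls in these data. Alternatives were median-ratio and upper-quartile scaling, library sizes without acinar and insulin genes, no filter and a filter at 1 CPM, sample quality weights, the acinar score as a covariate, a test against a log2 fold change of 0.5, and leaving out each replicate. After the data were seen, the fit with all 6 columns, a trimmed mean of M values, other added constants (0.5 and 2), a prior with no trend, median-ratio scaling of protein-coding genes without acinar and histone genes, and removal of length and GC trends in protein-coding genes were added.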

Results

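Gene expression was measured by RNA sequencing of isolated pancreatic islets from C57BL6 mice in 2 groups of 3 samples each. One group ate normal chow, and the other ate a high-fat diet with 60 percent of its calories from fat for 4 months, starting at the age of 3 months. The labels used here give no age or feeding time for the chow mice, so whether the groups matched in age is not known. The series title names palmitic acid, AKT and mTOR in beta-cells, and the question the groups address is how islet transcripts differ between the diets. The deposited table held CPM (read counts scaled to the total of the library) for 48321 gene names. The spacing of the low values gave implied totals of 18.8 and 24.7 M reads for chow replicates 1 and 3, and 23.7, 35.1 and 23.5 M reads for high-fat replicates 1, 2 and 3. Chow replicate 2 equalled the arithmetic mean of chow replicates 1 and 3 in 48321 of 48321 gene names. It was therefore not counted as an independent library, and chow had n = 2 and high-fat diet n = 3 throughout.

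The high-fat libraries held several small structured non-coding RNAs that were nearly absent from the chow libraries. Rn7sk, which inhibits transcription elongation, was at 6.27 and 13.3 CPM in chow replicates 1 and 3 and at 3626, 3192 and 3935 CPM in the high-fat replicates. Rpph1, the RNA of ribonuclease P, was at 0.425 and 0.081 CPM against 4082, 3294 and 3663 CPM, and Rmrp was at 0.314 and 0.0405 CPM against 622, 521 and 397 CPM. Rn7s1 and Rn7s2, near-identical copies of the signal recognition particle RNA whose reads cannot be separated, averaged 1.04 and 1.29 CPM in chow and 9216 and 9216 CPM on the high-fat diet. These RNAs are not polyadenylated. They separated the libraries exactly as the diet did, and the sample names also changed their prefix with the diet. A difference in library type and a difference in diet can therefore not be told apart for any gene below.

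**Figure D1:**
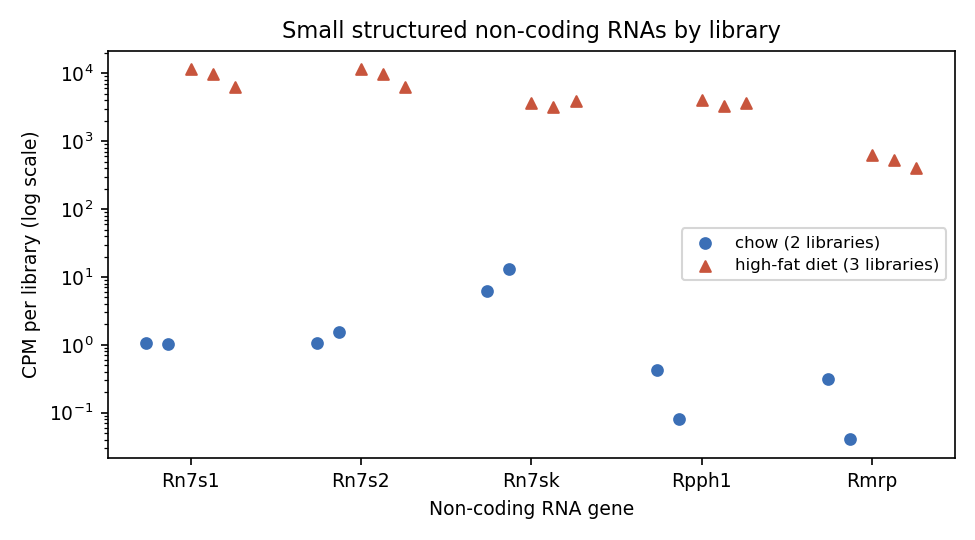
CPM (log axis) of 5 small structured non-coding RNAs in each independent library, with circles for the 2 chow libraries and triangles for the 3 high-fat libraries. For Rn7sk the chow libraries lay at 6.27 and 13.3 CPM and the lowest high-fat library at 3192 CPM.

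Transcripts of exocrine acinar cells, the enzyme-secreting cells around the islets, took up very different shares of the libraries. The acinar markers made up 27.5% and 10.6% of the summed gene CPM in chow replicates 1 and 3, and 11.8%, 1.6% and 4.73% in high-fat replicates 1, 2 and 3. The means were 19.1% ± 11.9 (SD, n = 2) and 6.04% ± 5.22 (SD, n = 3), a difference within the spread of the libraries (exact two-sided permutation p = 0.4, adjusted p = 0.8 over 2 tests). Ins1 and Ins2 together made up 7.56% ± 2.91 (SD, n = 2) and 8.25% ± 0.993 (SD, n = 3; exact two-sided permutation p = 0.8, adjusted p = 0.8). With 2 libraries against 3, the smallest p of this test is 0.2. The acinar difference of -13 percentage points became -4.6 without chow replicate 1 and -21.5 without chow replicate 3. For the insulin genes the difference of 0.689 turned to -1.37 without chow replicate 1 and was 2.75 without chow replicate 3. The mitochondrially encoded genes are listed at 0 in every library, so their share could not be compared.

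**Figure D2:**
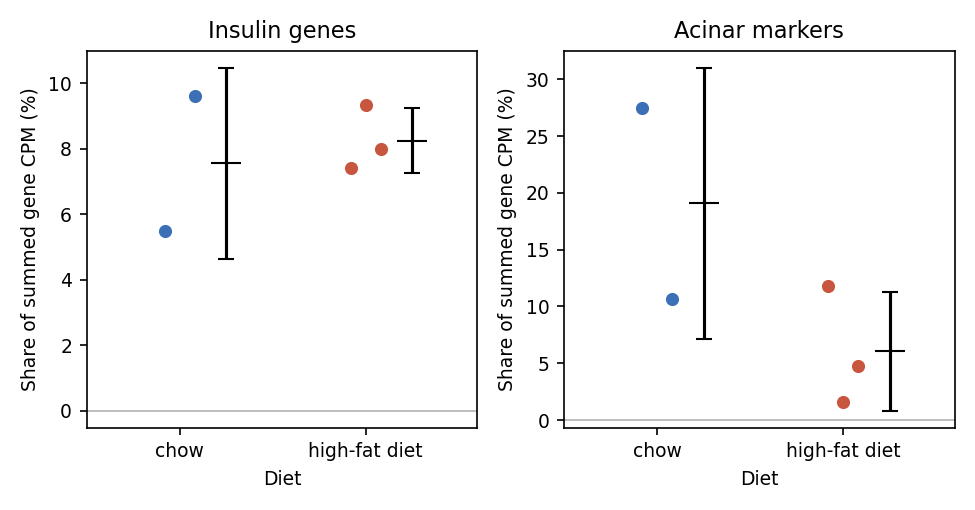
Share of the summed gene CPM (percent) in the insulin genes (left) and the acinar markers (right) for each independent library by diet, with the mean and SD beside the points. The acinar share reached 27.5% in 1 chow library and 1.6% in 1 high-fat library.

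With the deposited CPM, 16 of 20 cholesterol synthesis genes and 9 of 24 insulin signalling genes, among them Akt2, were higher in high-fat islets, and 8 of 17 immediate early genes, 11 of 23 fibroblast genes and the metallothioneins Mt1 and Mt2 were lower. With acinar and insulin genes out of the library size, 6 cholesterol synthesis genes were higher and 0 lower, and 3 insulin signalling genes were higher and 6 lower. Insig1, a sterol sensor, went from 76.5 ± 12 CPM in chow to 213 ± 20.7 CPM on the high-fat diet, and Akt2, a kinase downstream of the insulin receptor, from 50.8 ± 1.04 CPM in chow to 122 ± 8.37 CPM on the high-fat diet. Mt1, a metal-binding metallothionein, went from 395 ± 29.3 CPM in chow to 70.1 ± 22.3 CPM on the high-fat diet (SD, n = 2 and 3). Of 16939 genes tested with limma, 2524 were higher and 1487 lower on the high-fat diet at a Benjamini-Hochberg adjusted p below 0.05. Among protein-coding genes these were 2048 and 1157. The diets did not overlap in 55.4% of the tested genes, against 20% by chance for 2 libraries against 3. In 4011 of the 4011 genes past the threshold the 3 high-fat libraries lay on 1 side of both chow libraries. A small p with so few libraries all but requires this, so it adds no support.

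The balance of the 2 directions depended on the scaling of the libraries. Higher genes were 62.9% of the calls with the deposited CPM, 50.6% (1990 higher and 1946 lower) with median-ratio scaling and 52.2% (1981 and 1811) with a trimmed mean of M values. When the library size was the summed CPM of all genes but the acinar and insulin genes, the median log2 fold change of all genes moved from 0.05 to -0.34, and 788 genes were higher and 6932 lower (10.2% higher). None of the genes called with the deposited CPM was called in the other direction in that setting. That setting also scaled by the summed gene CPM, which differed between libraries before any gene was left out. The sum was 841705 and 674482 in chow replicates 1 and 3, and 963615, 832416 and 879301 in the high-fat replicates. The shift in that setting is therefore not owed to the acinar and insulin genes alone. That library size still held Gm26917 and the 5 small RNAs. Gm26917 took 0.0096% and 0.0136% of the summed CPM in chow replicates 1 and 3, and 3.67%, 4.26% and 4.64% in the high-fat replicates. Fold changes, medians and tallies given for that setting hold this shift of all genes. Leaving out any library but chow replicate 3 lowered the counts by over 1.5 times. They were 1344 higher and 780 lower without chow replicate 1, 1441 and 790 without high-fat replicate 1, 1167 and 682 without replicate 2, and 1222 and 745 without replicate 3. Without chow replicate 3 they were 2969 and 1415. With the acinar score as a covariate, 1169 genes were higher and 761 lower. With all 6 columns, the averaged one taken as a further chow library, they were 4224 and 2828.

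Apart from predicted genes, clone names and pseudogenes, which the rule for named genes left out, the largest increases were in the small RNAs above and 5 protein-coding genes. Pou4f1, a neuronal transcription factor, was at 0.342 and 0.212 CPM in the chow libraries and at 1479.5 ± 325 CPM (SD, n = 3) on the high-fat diet, and Ccdc154 at 0.16 and 0.325 against 402 ± 47.4 CPM. Dpysl3 went from 11.8 ± 1.13 CPM in chow to 3048 ± 1161 CPM on the high-fat diet, Adgrb2 from 1.42 ± 0.261 CPM in chow to 298 ± 72.6 CPM on the high-fat diet, and Zfp654 from 35.7 ± 2.46 CPM in chow to 4125 ± 749 CPM on the high-fat diet. The largest decreases by the same rule were in AY036118, listed at 0 in the 3 high-fat libraries and at 17.2 and 63.7 CPM in chow, and in Lars2, the mitochondrial leucyl-tRNA synthetase (1365 to 66.4 CPM). Mir6236 (145 to 6.95 CPM), Mir6240 (41.3 to 2.17 CPM), Dhx58os (40.5 to 1.44 CPM) and AA474408 (87.6 to 7.31 CPM) fell as well. Whether the reads listed under AY036118, Lars2, Mir6236 and Mir6240 came from these genes or from other RNAs with shared sequence was not tested. Vip, a neuropeptide, fell from 39.2 ± 1.01 CPM in chow to 1.79 ± 0.329 CPM on the high-fat diet, and Tmsb15b2 went from 24.2 to 1.53 CPM. The acinar-associated genes Reg2 (618 to 35.1 CPM) and Prss3 (40.4 to 2.08 CPM) fell beside the lower mean acinar share of the high-fat libraries. Reg2 lost its call without chow replicate 1 and high-fat replicate 3 (limma adjusted p = 0.114 and 0.0699). Lars2 (0.054), Reg2 (0.104) and Prss3 (0.0551) lost their calls with no filter, with adjusted p in brackets (limma for genes).

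Some insulin signalling genes were higher in high-fat islets with the deposited CPM. Of 24 tested genes of the insulin, PI3K and AKT list, 9 rose and 0 fell over all genes tested, and 13 rose and 2 fell adjusted over the list alone. Phlpp1, a phosphatase that removes an activating phosphate from AKT, rose by 1.97 ± 0.11 on the log2 scale (SE; 17.5 to 71.1 CPM, adjusted p = 7.56e-05, limma). Akt2 rose by 1.24 ± 0.09 (adjusted p = 0.000214), the PI3K subunit Pik3r2 by 0.69 ± 0.07, and the insulin receptor substrates Irs2 and Irs1 by 0.82 ± 0.09 and 0.84 ± 0.18. Akt1 (0.15 ± 0.08, adjusted p = 0.208), Insr (0.28 ± 0.22, 0.384) and Foxo1 (0.01 ± 0.11, 0.97) did not pass the threshold. The list was called higher by camera (adjusted p = 0.0040), with adjusted p = 0.861 with an estimated correlation. Its median log2 fold change was 0.31. Under the scaling without acinar and insulin genes, the tally became 3 higher and 6 lower for the insulin signalling list. This ended the calls of Pik3r2 (0.0857) and Irs1 (0.125), with limma's adjusted p in brackets. Calls were gained by Akt1 (0.0294, log2 -0.31) and Foxo1 (0.0255, log2 -0.46) (limma adjusted p). That scaling put below 0 the median of the insulin signalling list (-0.14). It ended the call of the insulin signalling list (camera adjusted p = 0.0527). Relative to the median of all genes, the median of the list went from 0.26 to 0.20. Irs1 (0.0742) lost its call with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Irs1 (0.0834) did so with no filter. The insulin signalling list (0.0717) did so with the test fry in place of camera. Irs1 lost its call without high-fat replicates 1, 2 and 3 (limma adjusted p = 0.0543, 0.0541 and 0.0656). Insr gained a call without chow replicate 3 (limma adjusted p = 0.00861).

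A few genes of the mTOR complexes moved, in both directions, with the deposited CPM. Of 31 tested, 5 rose and 3 fell over all genes tested, and 5 rose and 3 fell adjusted over the list alone. Mtor itself rose by 0.42 ± 0.12 (log2, SE; adjusted p = 0.0427, limma), Rps6, a ribosomal target of the pathway, by 0.72 ± 0.17 and Rraga, a GTPase of amino acid sensing, by 0.33 ± 0.09. Rps6kb1, the S6 kinase, changed by -0.46 ± 0.12 and the cap-binding Eif4e by -0.28 ± 0.08. The list was not called (camera adjusted p = 0.632). Of 15 FOXO targets, 2 rose and 1 fell over all genes tested, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.546). Irs2 and Txnip, an inhibitor of thioredoxin (0.62 ± 0.13), rose, Cat, the catalase gene (-1.03 ± 0.26), fell, and Cdkn1a was at 0.64 ± 0.30 (adjusted p = 0.156). When acinar and insulin genes were left out of the library size, the tally became 0 higher and 14 lower for the mTOR list and 1 higher and 6 lower for the FOXO target list. There, limma's adjusted p no longer passed for Mtor (0.828), Rps6 (0.212), Rraga (0.393) and Txnip (0.399). Then also below 0 lay the medians of the mTOR list (-0.38) and the FOXO target list (-0.30) and the fold changes of Mtor (-0.04) and Rraga (-0.13). Less the median of all genes, the mTOR median went from 0.03 to -0.04 and the FOXO target median from 0.11 to 0.04. Under median-ratio scaling, the tally was 1 higher and 3 lower for the mTOR list and calls ended for Mtor (0.0594, and 0.066 with a trimmed mean of M values) and Rraga (0.0592, and 0.0619 with a trimmed mean of M values), with adjusted p in brackets. Mtor (0.173), Rraga (0.184), Rps6kb1 (0.114), Eif4e (0.139) and Cat (0.0924) lost their calls with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Mtor (0.118), Rps6 (0.0533), Rps6kb1 (0.0793) and Eif4e (0.108) did so after removal of length and GC trends in protein-coding genes. Mtor (0.129), Rps6 (0.0996), Rraga (0.106), Rps6kb1 (0.0996), Eif4e (0.0674), Txnip (0.0612) and Cat (0.118) did so with no filter. Rraga (0.0557) and Eif4e (0.0528) did so with sample quality weights. Mtor (0.0795), Rraga (0.085), Rps6kb1 (0.0587) and Eif4e (0.0816) did so with no trend in the variance prior. Mtor (0.0531) and Rraga (0.052) did so with median-ratio scaling of protein-coding genes without acinar and histone genes. Without chow replicate 1, calls ended for Mtor (0.127), Rps6 (0.0569), Rraga (0.148), Rps6kb1 (0.142), Eif4e (0.0956) and Cat (0.125), with limma's adjusted p in brackets. Those of Rps6 (0.0741) and Eif4e (0.0523) ended without chow replicate 3. Those of Mtor (0.094), Rraga (0.0682), Rps6kb1 (0.0849), Eif4e (0.105), Txnip (0.062) and Cat (0.0549) ended without high-fat replicate 1. Those of Mtor (0.124), Rps6 (0.0722), Rraga (0.135), Rps6kb1 (0.0661), Eif4e (0.119), Txnip (0.064) and Cat (0.0944) ended without high-fat replicate 2. Those of Mtor (0.116), Rraga (0.115), Rps6kb1 (0.102), Eif4e (0.0931) and Cat (0.0843) ended without high-fat replicate 3. Cdkn1a gained a call without high-fat replicate 2 (limma adjusted p = 0.0398).

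With the deposited CPM, most cholesterol synthesis genes rose. Of 20 tested, 16 rose and 0 fell over all genes tested, and 18 rose and 0 fell adjusted over the list alone. Insig1 rose by 1.47 ± 0.13 (log2, SE; adjusted p = 0.000589, limma), the isomerase Idi1 by 1.28 ± 0.09 (10.6 to 27.2 CPM) and lanosterol synthase Lss by 0.83 ± 0.10. The list was called higher (camera adjusted p = 6.98e-08), with adjusted p = 0.861 with an estimated correlation. Its median was 0.78, and 0.32 with acinar and insulin genes left out of the library size. Of 18 fatty acid and triglyceride synthesis genes, 3 rose and 3 fell over all genes tested, and 5 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.992, with a median of 0.06 against a camera direction of lower). Fatty acid synthase Fasn rose by 1.03 ± 0.18, the desaturase Scd2 by 0.60 ± 0.11 and the elongase Elovl6 by 0.41 ± 0.10, and the acyltransferase Dgat2 changed by -0.84 ± 0.15. Of 27 fatty acid oxidation and PPAR target genes, 1 rose and 1 fell over all genes tested, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.284), the riser being Eci1 (8.89 to 56 CPM) and the other Acaa2 (29 to 22.3 CPM). In the scaling without acinar and insulin genes, the tally became 6 higher and 0 lower for the cholesterol synthesis list, 1 higher and 9 lower for the fatty acid synthesis list and 1 higher and 18 lower for the fatty acid oxidation list. Calls then ended for Scd2 (0.437) and Elovl6 (0.817), with limma's adjusted p in brackets. That scaling put below 0 the median of the fatty acid synthesis list (-0.35) and the fold change of Elovl6 (-0.04). The median of that list relative to all genes went from 0.003 to -0.009. With median-ratio scaling, the tally was 1 higher and 4 lower for the fatty acid oxidation list and calls ended for Elovl6 (0.0567, and 0.0504 with a trimmed mean of M values), with adjusted p in brackets. Elovl6 (0.106) lost its call with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Fasn (0.0569), Scd2 (0.0555) and Elovl6 (0.0877) did so with no filter. Elovl6 (0.0507) did so with sample quality weights. Elovl6 (0.0584) did so with no trend in the variance prior. Elovl6 lost its call without chow replicates 1 and 3 and high-fat replicates 1, 2 and 3 (limma adjusted p = 0.0785, 0.0746, 0.0544, 0.0787 and 0.0875).

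With the deposited CPM, several beta-cell genes were higher in high-fat islets, while several genes normally kept low in beta-cells (disallowed genes) were lower. Of 22 beta-cell identity genes, 7 rose and 0 fell over all genes tested, and 7 rose and 0 fell adjusted over the list alone. Mafa, an activator of insulin transcription, rose from 75.2 ± 3.48 CPM in chow to 107 ± 4.71 CPM on the high-fat diet (SD, n = 2 and 3), the potassium channel subunit Kcnj11 by 0.48 ± 0.09 (log2, SE), the incretin receptor Glp1r by 0.39 ± 0.09, the prohormone convertase Pcsk1 by 0.56 ± 0.14 and the transcription factor Pdx1 by 0.59 ± 0.17 (adjusted p = 0.0429, limma). The glucose transporter Slc2a2 was at -0.24 ± 0.17 (adjusted p = 0.328). The list was not called (camera adjusted p = 0.233), and its median of 0.36 became -0.11 with acinar and insulin genes left out of the library size. Relative to all genes, which moved down together, its median went from 0.31 to 0.24. Of 20 disallowed genes, 0 rose and 10 fell over all genes tested, and 0 rose and 12 fell adjusted over the list alone, with Acot7 at -1.09 ± 0.16, Nfib at -0.91 ± 0.17, lactate dehydrogenase Ldha at -1.05 ± 0.20 and Zfp36l1 at -1.05 ± 0.21. That list was called lower (camera adjusted p = 1.36e-05, and adjusted p = 0.861 with an estimated correlation). Some markers of other cell types were lower beside it, with 11 of 23 fibroblast and 4 of 14 endothelial genes lower, 0 higher in either list, and an acinar median of -1.49. Nfib (22.7 and 17.5 CPM), Ldha (13 and 8.6) and Zfp36l1 (17.7 and 10.7) were higher in chow replicate 1 than in chow replicate 3, as were the fibroblast gene Dcn (60.9 and 21.1) and the acinar share (27.5% and 10.6%). With acinar and insulin genes out of the library size, the tally became 0 higher and 7 lower for the beta-cell identity list and 0 higher and 16 lower for the disallowed gene list. This ended the calls of Mafa (0.769), Kcnj11 (0.903), Glp1r (0.591), Pcsk1 (0.642) and Pdx1 (0.602), with limma's adjusted p in brackets. Calls were gained by Slc2a2 (0.0188, log2 -0.71) (limma adjusted p). Then also below 0 lay the median of the beta-cell identity list (-0.11) and the fold change of Glp1r (-0.08). Under median-ratio scaling, calls ended for Pdx1 (0.0526, and 0.0568 with a trimmed mean of M values), with adjusted p in brackets. Glp1r (0.0778), Pcsk1 (0.085) and Pdx1 (0.147) lost their calls with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Mafa (0.0905), Glp1r (0.0569) and Pdx1 (0.0808) did so after removal of length and GC trends in protein-coding genes. Glp1r (0.0651), Pcsk1 (0.0946), Pdx1 (0.146), Nfib (0.0549), Ldha (0.0568) and Zfp36l1 (0.0684) did so with no filter. Pdx1 (0.0737) did so with no trend in the variance prior. The disallowed gene list (0.122) did so with the test fry in place of camera. Calls ended for Glp1r (0.0665), Pcsk1 (0.0694), Pdx1 (0.13), Nfib (0.0556), Ldha (0.0546) and Zfp36l1 (0.0502) without chow replicate 1, with limma's adjusted p in brackets. Those of Glp1r (0.0725), Pcsk1 (0.0856) and Pdx1 (0.0828) ended without high-fat replicate 1. Those of Kcnj11 (0.0556), Glp1r (0.0733), Pcsk1 (0.0829), Pdx1 (0.129) and Zfp36l1 (0.0545) ended without high-fat replicate 2. Those of Glp1r (0.0845), Pcsk1 (0.0814), Pdx1 (0.102) and Zfp36l1 (0.0513) ended without high-fat replicate 3. Slc2a2 gained a call without chow replicate 1 (limma adjusted p = 0.0396). The beta-cell identity list gained a call without chow replicate 3 (camera adjusted p = 0.0374).

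The hormone genes did not pass the threshold. Ins1 was at 20649 ± 4472 CPM in chow and 30489 ± 1679 CPM on the high-fat diet (adjusted p = 0.805, limma), and Ins2 at 34915 ± 8680.4 and 42641 ± 2442 CPM (adjusted p = 0.927). With no trend in the variance prior their adjusted p was 0.0503 and 0.235. Glucagon, Gcg, was at 10102 and 2332 CPM in chow replicates 1 and 3 and at 11338 ± 747 CPM on the high-fat diet (adjusted p = 0.306). Pancreatic polypeptide, Ppy, was at 854 and 2907 CPM in the same chow libraries and 1042 ± 106 CPM on the high-fat diet (0.387), and somatostatin, Sst, at 898 and 798 CPM (0.499). Of 8 alpha-cell markers, 2 rose and 0 fell over all genes tested, and 2 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0835), namely Ttr (359 to 1137 CPM) and Etv1 (30.7 to 50.3 CPM). Of 7 delta-, PP- and epsilon-cell markers, 1 rose and 0 fell over all genes tested, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.512, median -0.46, mean 0.06), the riser being the retinol carrier Rbp4 (40.6 to 353 CPM). Of 8 dedifferentiation genes, 2 rose and 0 fell over all genes tested, and 2 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.246), namely Aldh1a3 (3.23 to 14.6 CPM) and Sox9 (5.88 to 14.9 CPM). Of 23 secretory granule and exocytosis genes, 6 rose and 2 fell over all genes tested, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.201). Rims2, Unc13a and Ptprn, which act in vesicle docking, priming and granules, rose by 0.65 ± 0.08, 1.24 ± 0.16 and 0.67 ± 0.12, and Cplx1, a complexin of vesicle fusion, fell (-1.62 ± 0.21, 4.92 to 0.92 CPM). Under the scaling without acinar and insulin genes, the tally became 1 higher and 0 lower for the alpha-cell list, 1 higher and 3 lower for the delta-, PP- and epsilon-cell list, 1 higher and 2 lower for the dedifferentiation list and 1 higher and 7 lower for the secretory list. There, limma's adjusted p no longer passed for Rims2 (0.143) and Ptprn (0.261). Calls were gained by Sst (0.029, log2 -0.65) (limma adjusted p). That scaling put below 0 the median of the secretory list (-0.18). It gave the call of the alpha-cell list (camera adjusted p = 0.00343) and the dedifferentiation list (camera adjusted p = 0.0486). Relative to all genes, the secretory median went from 0.24 to 0.16. The alpha-cell list (0.0172) gained a call with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). The alpha-cell list (0.0289) did so with no filter. The dedifferentiation list (0.0314) did so with the test fry in place of camera. Without chow replicate 1, calls were gained for Ppy (0.0099) and the alpha-cell list (5.52e-05), with adjusted p (limma for genes, camera for lists) in brackets. For the secretory list (0.0372) this held without chow replicate 3.

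Several markers of connective tissue and vessels were lower in high-fat islets. Of 23 fibroblast, stellate and matrix genes, 0 rose and 11 fell over all genes tested, and 0 rose and 19 fell adjusted over the list alone. The matrix genes Dcn, Bgn and Col3a1 changed by -2.75 ± 0.45, -1.74 ± 0.35 and -1.41 ± 0.28 (log2, SE), and Thy1 by -1.52 ± 0.23 (8.5 to 2.29 CPM). The list was called lower (camera adjusted p = 4.52e-08, and adjusted p = 0.861 with an estimated correlation). Of 14 endothelial markers, 0 rose and 4 fell over all genes tested, and 0 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.00368, and adjusted p = 0.861 with an estimated correlation), namely Tek (-0.81 ± 0.15), Vwf (-1.35 ± 0.36), Eng (-0.50 ± 0.13) and Pecam1 (-0.43 ± 0.12). When acinar and insulin genes were left out of the library size, the tally became 0 higher and 22 lower for the fibroblast list and 0 higher and 13 lower for the endothelial list. Bgn (0.0545), Vwf (0.0801) and Pecam1 (0.109) lost their calls with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Dcn (0.0523), Bgn (0.0781), Col3a1 (0.0739), Vwf (0.133), Eng (0.122) and Pecam1 (0.133) did so with no filter. Vwf (0.0577), Eng (0.0697) and Pecam1 (0.0658) did so with sample quality weights. Vwf (0.0549), Eng (0.068) and Pecam1 (0.0806) did so with no trend in the variance prior. The fibroblast list (0.122) and the endothelial list (0.198) did so with the test fry in place of camera. Calls ended for Bgn (0.0592), Col3a1 (0.0683), Tek (0.0593), Vwf (0.176), Eng (0.0855) and Pecam1 (0.189) without chow replicate 1, with limma's adjusted p in brackets. Those of Eng (0.104) ended without chow replicate 3. Those of Vwf (0.0651), Eng (0.0919) and Pecam1 (0.112) ended without high-fat replicate 1. Those of Bgn (0.0539), Col3a1 (0.051), Vwf (0.0932) and Pecam1 (0.107) ended without high-fat replicate 2. Those of Eng (0.109) and Pecam1 (0.0629) ended without high-fat replicate 3. Of 8 Schwann and glial markers, 2 rose and 4 fell over all genes tested, and 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.198). Cdh19 and Sox10 changed by -1.24 ± 0.16 and -0.82 ± 0.16. Of 18 macrophage and myeloid markers, 1 rose and 2 fell over all genes tested, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.54, median 0.01, mean -0.05). The complement gene C1qa was at 0.56 ± 0.11, Mrc1 at -0.96 ± 0.19 and Itgam at -0.57 ± 0.16, and C1qb at 0.48 ± 0.18 did not pass (adjusted p = 0.0938). In the scaling without acinar and insulin genes, the tally became 1 higher and 5 lower for the Schwann list and 0 higher and 7 lower for the macrophage list. This ended the calls of C1qa (0.523), with limma's adjusted p in brackets. That scaling put below 0 the median of the macrophage list (-0.35). Less the median of all genes, it went from -0.05 to -0.004. C1qa (0.0729), Mrc1 (0.0547) and Itgam (0.117) lost their calls with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). C1qa (0.0569) did so after removal of length and GC trends in protein-coding genes. Sox10 (0.0863), C1qa (0.0646), Mrc1 (0.0742) and Itgam (0.17) did so with no filter. Itgam (0.0562) did so with a filter at 1 CPM. Itgam (0.0717) did so with sample quality weights. C1qb (0.0355) gained a call with all 6 columns. Without chow replicate 1, calls ended for Mrc1 (0.0681) and Itgam (0.169), with limma's adjusted p in brackets. Those of Sox10 (0.0511) and Itgam (0.0832) ended without chow replicate 3. Those of Itgam (0.109) ended without high-fat replicate 1. Those of C1qa (0.0615) and Itgam (0.116) ended without high-fat replicate 2. Those of Sox10 (0.0505), C1qa (0.0615) and Itgam (0.0703) ended without high-fat replicate 3. C1qb gained a call without high-fat replicate 1 (limma adjusted p = 0.0296).

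The share of acinar transcripts averaged 19.1% in chow and 6.04% on the high-fat diet. Of 29 acinar markers, 1 rose and 0 fell over all genes tested, and 0 rose and 0 fell adjusted over the list alone, the riser being the transcription factor Bhlha15 (0.95 ± 0.22, log2, SE). The list had a median of -1.49 and was called lower (camera adjusted p = 0.000597, and adjusted p = 0.861 with an estimated correlation). Spink1 (-2.49 ± 0.78), Gp2 (-2.74 ± 0.94) and the amylase gene Amy2a5 (-2.74 ± 0.95, adjusted p = 0.0767) had the next smallest p and did not pass. Of 11 duct markers, 3 rose and 2 fell over all genes tested, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.401). Prom1 rose from 30.1 to 88.8 CPM, and Sox9 (1.25 ± 0.34) and Spp1 (-1.0 ± 0.28) passed as well. Of 7 lymphocyte markers, 1 rose and 1 fell over all genes tested, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.626, median -0.28, mean 0.10), with Cd3e up (0.168 to 3.72 CPM) and Cd79a down (12.8 to 7.94 CPM). Of 5 erythroid markers, 2 rose and 0 fell over all genes tested, and 3 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0941). The 2 past the threshold over all genes were Hbb-bs (12.8 to 29.2 CPM) and Hba-a2 (9.89 to 20.3 CPM), globin genes with close copies. Of 4 adipocyte markers, too few for the list test, Fabp4 fell (17.5 to 8.32 CPM). With acinar and insulin genes out of the library size, the tally became 0 higher and 7 lower for the acinar list, 1 higher and 6 lower for the duct list, 1 higher and 3 lower for the lymphocyte list and 0 higher and 0 lower for the erythroid list. There, limma's adjusted p no longer passed for Bhlha15 (0.0707) and Sox9 (0.0575). Calls were gained by Spink1 (0.0122, log2 -2.93), Gp2 (0.0185, log2 -3.21) and Amy2a5 (0.0199, log2 -3.21) (limma adjusted p). The call of the acinar list (camera adjusted p = 0.497) was lost. The median of the acinar list went from -1.49 to -1.96, and relative to all genes from -1.54 to -1.62. The call of the erythroid list (camera adjusted p = 0.00511) was gained. Under median-ratio scaling, the tally was 1 higher and 2 lower for the duct list and calls ended for Sox9 (0.0566, and 0.0523 with a trimmed mean of M values), with adjusted p in brackets. The acinar score is the mean log2 value of these acinar markers, so as a covariate it removes the mean diet effect of their list by construction. Spp1 (0.154) and the acinar list (0.881) lost their calls with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Sox9 (0.0625) and Spp1 (0.0722) did so after removal of length and GC trends in protein-coding genes. Bhlha15 (0.102), Sox9 (0.143) and Spp1 (0.159) did so with no filter. Sox9 (0.0534) did so with sample quality weights. Sox9 (0.0613) and Spp1 (0.0721) did so with no trend in the variance prior. Sox9 (0.0529) did so with median-ratio scaling of protein-coding genes without acinar and histone genes. The acinar list (0.475) did so with the test fry in place of camera. Spink1 (0.0169), Gp2 (0.00507) and Amy2a5 (0.0198) gained calls with the acinar score as a covariate. The erythroid list (0.0483) did so with no filter. Spink1 (0.0241), Gp2 (0.0341) and Amy2a5 (0.0313) did so with all 6 columns. Calls ended for Bhlha15 (0.050), Spp1 (0.159) and the acinar list (0.143) without chow replicate 1, with adjusted p (limma for genes, camera for lists) in brackets. Those of Bhlha15 (0.0791) and Sox9 (0.13) ended without chow replicate 3. Those of Sox9 (0.0953) and Spp1 (0.0819) ended without high-fat replicate 1. Those of Sox9 (0.051) and Spp1 (0.0877) ended without high-fat replicate 2. Those of Bhlha15 (0.0742), Sox9 (0.0997) and Spp1 (0.123) ended without high-fat replicate 3. Without chow replicate 3, calls were gained for Spink1 (0.0395), with adjusted p (limma for genes, camera for lists) in brackets. For Spink1 (0.0241), Gp2 (0.0334), Amy2a5 (0.0471) and the erythroid list (0.00763) this held without high-fat replicate 1.

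With the deposited CPM, genes of energy metabolism and translation did not share a direction. Of 17 glycolysis genes, 5 rose and 2 fell over all genes tested, and 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.288). Hexokinase 2, Hk2, rose from 3.92 ± 0.51 CPM in chow to 64.2 ± 6.15 CPM on the high-fat diet (SD, n = 2 and 3), Eno1 by 0.96 ± 0.14 (log2, SE) and Gapdh by 0.78 ± 0.15, and Ldha fell. Gapdh averaged 9.56 CPM on the high-fat diet. Of 36 nuclear genes of oxidative phosphorylation, 4 rose and 4 fell over all genes tested, and 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.54), with Atp5o (0.44 ± 0.10) higher and Atp5c1 (-0.66 ± 0.08) and Ndufb10 (-0.58 ± 0.10) lower. Of 75 cytosolic ribosomal protein genes, 12 rose and 17 fell over all genes tested, and 13 rose and 21 fell adjusted over the list alone. Rpl24 (-1.99 ± 0.24), Rpl30 (-1.43 ± 0.14), Rpl27a (-0.87 ± 0.09) and Rps21 (-0.76 ± 0.08) had the smallest p. The list was called lower with a median of -0.04 (camera adjusted p = 0.0411, and adjusted p = 0.88 with an estimated correlation). A median of 42.7% of the 31-base words of these genes also occurred in other annotated genes, against 2.41% for oxidative phosphorylation and 16% for glycolysis, so that their values depend on how shared reads were assigned. Under the scaling without acinar and insulin genes, the tally became 2 higher and 6 lower for the glycolysis list, 0 higher and 25 lower for the oxidative phosphorylation list and 3 higher and 48 lower for the ribosomal protein list. Calls then ended for Gapdh (0.101) and Atp5o (0.936), with limma's adjusted p in brackets. That scaling put below 0 the median of the glycolysis list (-0.23) and the fold change of Atp5o (-0.01). It gave the call of the oxidative phosphorylation list (camera adjusted p = 0.0167). The glycolysis median relative to all genes went from 0.15 to 0.12. With median-ratio scaling, the call ended for the ribosomal protein list (0.0512, median -0.11), with adjusted p in brackets. Gapdh (0.0514), Atp5o (0.0539), Ndufb10 (0.0525) and the ribosomal protein list (0.511) lost their calls with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). The ribosomal protein list (0.0708, median relative to all genes -0.12, from -0.09) did so after removal of length and GC trends in protein-coding genes. Ldha (0.0568) and Atp5o (0.0629) did so with no filter. The ribosomal protein list (0.0534) did so with median-ratio scaling of protein-coding genes without acinar and histone genes. The ribosomal protein list (0.0637) did so with all 6 columns. The ribosomal protein list (0.475) did so with the test fry in place of camera. The glycolysis list (0.0478) gained a call with the test fry in place of camera. Calls ended for Gapdh (0.053), Ldha (0.0546), Atp5o (0.073) and the ribosomal protein list (0.841) without chow replicate 1, with adjusted p (limma for genes, camera for lists) in brackets. Those of Atp5o (0.0658) ended without high-fat replicate 1. Those of Atp5o (0.0656) and the ribosomal protein list (0.0764) ended without high-fat replicate 2. Those of the ribosomal protein list (0.151) ended without high-fat replicate 3.

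Some genes of the unfolded protein response were higher with the deposited CPM, and some immediate early genes lower, in high-fat islets. Of 22 genes of the unfolded protein response, 7 rose and 0 fell over all genes tested, and 7 rose and 0 fell adjusted over the list alone. The chaperone Hyou1 rose by 1.03 ± 0.14 (log2, SE; 338 to 688 CPM), Manf by 0.73 ± 0.10, Pdia4 by 0.71 ± 0.08 and Sdf2l1 by 0.70 ± 0.09 (largest adjusted p = 0.00406, limma). The list was called higher (camera adjusted p = 0.0274, adjusted p = 0.861 with an estimated correlation). Of 17 immediate early and dissociation stress genes, 0 rose and 8 fell over all genes tested, and 0 rose and 10 fell adjusted over the list alone. Egr1, Fos, Zfp36 and Junb changed by -1.98 ± 0.33, -1.81 ± 0.27, -1.26 ± 0.21 and -1.19 ± 0.18. That list was called lower (camera adjusted p = 0.000125, and adjusted p = 0.861 with an estimated correlation). Of 25 targets of the integrated stress response, 3 rose and 2 fell over all genes tested, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.512). Ddit3 (-0.89 ± 0.14) and Vldlr (-0.53 ± 0.12) fell, and Aldh18a1 (0.58 ± 0.10) and Ppp1r15a (0.39 ± 0.09) rose. Of 21 antioxidant genes, 3 rose and 5 fell over all genes tested, and 5 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.383). Mt1 and Mt2 changed by -2.53 ± 0.26 and -2.54 ± 0.23, and the peroxidase Gpx4 and sulfiredoxin Srxn1 by 0.67 ± 0.08 and 0.57 ± 0.08. When acinar and insulin genes were left out of the library size, the tally became 1 higher and 6 lower for the unfolded protein response list, 0 higher and 13 lower for the immediate early list, 0 higher and 10 lower for the integrated stress response list and 0 higher and 13 lower for the antioxidant list. This ended the calls of Manf (0.0829), Pdia4 (0.0761), Sdf2l1 (0.0721), Aldh18a1 (0.348), Ppp1r15a (0.613), Gpx4 (0.107) and Srxn1 (0.365), with limma's adjusted p in brackets. Then also below 0 lay the median of the unfolded protein response list (-0.21) and the fold change of Ppp1r15a (-0.06). Relative to all genes, that median went from 0.19 to 0.13. The call of the unfolded protein response list (camera adjusted p = 0.332) was lost. Under median-ratio scaling, calls ended for Ppp1r15a (0.0528), with adjusted p in brackets. Vldlr (0.0801) lost its call with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Ppp1r15a (0.0677) did so after removal of length and GC trends in protein-coding genes. Egr1 (0.0544), Zfp36 (0.0515), Vldlr (0.0755) and Ppp1r15a (0.0571) did so with no filter. The unfolded protein response list (0.109) and the immediate early list (0.122) did so with the test fry in place of camera. Without chow replicate 1, calls ended for Vldlr (0.0677), with adjusted p (limma for genes, camera for lists) in brackets. Those of Ppp1r15a (0.0508) and the unfolded protein response list (0.131) ended without chow replicate 3. Those of Vldlr (0.063), Ppp1r15a (0.0735) and the unfolded protein response list (0.0676) ended without high-fat replicate 1. Those of Vldlr (0.0595) and Ppp1r15a (0.060) ended without high-fat replicate 2. Those of Ppp1r15a (0.0733) and the unfolded protein response list (0.065) ended without high-fat replicate 3.

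Of 28 cell cycle genes, 2 rose and 0 fell over all genes tested, and 1 rose and 0 fell adjusted over the list alone. E2f1, an activator of S-phase genes, rose by 1.42 ± 0.12 (log2, SE), Birc5 rose from 0.175 to 0.821 CPM, and Pcna (0.57 ± 0.17) and Mcm2 (0.46 ± 0.16) did not pass (adjusted p = 0.0532 and 0.0757, limma). The list was called higher (camera adjusted p = 0.0411, adjusted p = 0.862 with an estimated correlation). Of 24 interferon and antigen presentation genes, 4 rose and 2 fell over all genes tested, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.401). The interferon-induced Usp18, Irf7 and Cxcl10 rose by 1.24 ± 0.14, 1.27 ± 0.32 and 1.5 ± 0.37 and the proteasome subunit Psmb8 changed by -0.62 ± 0.14. Of 23 autophagy and lysosome genes, 3 rose and 1 fell over all genes tested, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.466). Neu1 (0.53 ± 0.09), Hexa (0.46 ± 0.08) and Gabarapl1 (0.39 ± 0.08) rose and the protease Ctsl (-0.43 ± 0.10) fell. Of 11 NF-kB and cytokine genes, 1 rose and 0 fell over all genes tested, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.992), and of 18 apoptosis and p53 genes, 1 rose and 0 fell over all genes tested, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.391). The risers were Nfkb1 (39.3 to 55.5 CPM) and Bbc3 (3.96 to 7.77 CPM). In the scaling without acinar and insulin genes, the tally became 2 higher and 2 lower for the cell cycle list, 3 higher and 7 lower for the interferon list, 0 higher and 13 lower for the autophagy list, 0 higher and 3 lower for the NF-kB list and 0 higher and 11 lower for the apoptosis list. There, limma's adjusted p no longer passed for Neu1 (0.615), Hexa (0.959) and Gabarapl1 (0.573). That scaling put below 0 the medians of the interferon list (-0.15), the autophagy list (-0.40) and the NF-kB list (-0.39) and the fold changes of Hexa (-0.01) and Gabarapl1 (-0.07). Less the median of all genes, these medians went from 0.10 to 0.20, from 0.02 to -0.05 and from -0.052 to -0.050. Birc5 (0.0876), Irf7 (0.112), Cxcl10 (0.0765), Psmb8 (0.0776), Ctsl (0.0905) and the cell cycle list (0.173) lost their calls with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). Birc5 (0.0781), Irf7 (0.118), Cxcl10 (0.126), Psmb8 (0.0566) and Ctsl (0.0757) did so with no filter. The cell cycle list (0.171) did so with a filter at 1 CPM. Irf7 (0.0504), Cxcl10 (0.0561) and the cell cycle list (0.0534) did so with sample quality weights. The cell cycle list (0.0637) did so with all 6 columns. The cell cycle list (0.267) did so with the test fry in place of camera. Pcna (0.0247) gained a call with the acinar score as a covariate. Pcna (0.033) did so after removal of length and GC trends in protein-coding genes. Pcna (0.0173) and Mcm2 (0.0203) did so with all 6 columns. The autophagy list (0.0127) did so with the test fry in place of camera. Calls ended for Birc5 (0.136), Irf7 (0.113), Cxcl10 (0.104), Psmb8 (0.0655), Ctsl (0.0618) and the cell cycle list (0.119) without chow replicate 1, with adjusted p (limma for genes, camera for lists) in brackets. Those of Irf7 (0.0722), Cxcl10 (0.0763), Psmb8 (0.0632) and the cell cycle list (0.12) ended without chow replicate 3. Those of Psmb8 (0.0612), Gabarapl1 (0.0661) and Ctsl (0.0658) ended without high-fat replicate 1. Those of Birc5 (0.0663), Irf7 (0.0928), Psmb8 (0.0687), Gabarapl1 (0.0628) and Ctsl (0.0787) ended without high-fat replicate 2. Those of Irf7 (0.0688), Gabarapl1 (0.0681), Ctsl (0.0804) and the cell cycle list (0.25) ended without high-fat replicate 3. Pcna gained a call without chow replicate 1 (limma adjusted p = 0.037). Mcm2 gained a call without chow replicate 3 (limma adjusted p = 0.0468).

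Several circadian clock genes changed, in opposite directions. Of 18 tested, 3 rose and 7 fell over all genes tested, and 3 rose and 8 fell adjusted over the list alone. Cry1 and Npas2 rose by 0.99 ± 0.11 and 1.31 ± 0.18 (log2, SE), and Nr1d1 and Hlf changed by -1.13 ± 0.14 and -1.0 ± 0.13 (largest adjusted p = 0.00394, limma). The list as a whole was not called (camera adjusted p = 0.0574). With acinar and insulin genes out of the library size, the tally became 3 higher and 13 lower for the clock list. The clock list (0.0355) gained a call with the acinar score as a covariate, with adjusted p in brackets (limma for genes, camera for lists). The clock list (0.0342) did so after removal of length and GC trends in protein-coding genes. The clock list (0.013) did so with no filter. The clock list gained a call without high-fat replicate 2 (camera adjusted p = 0.0473). The labels used here give no hour of islet isolation.

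**Figure D3:**
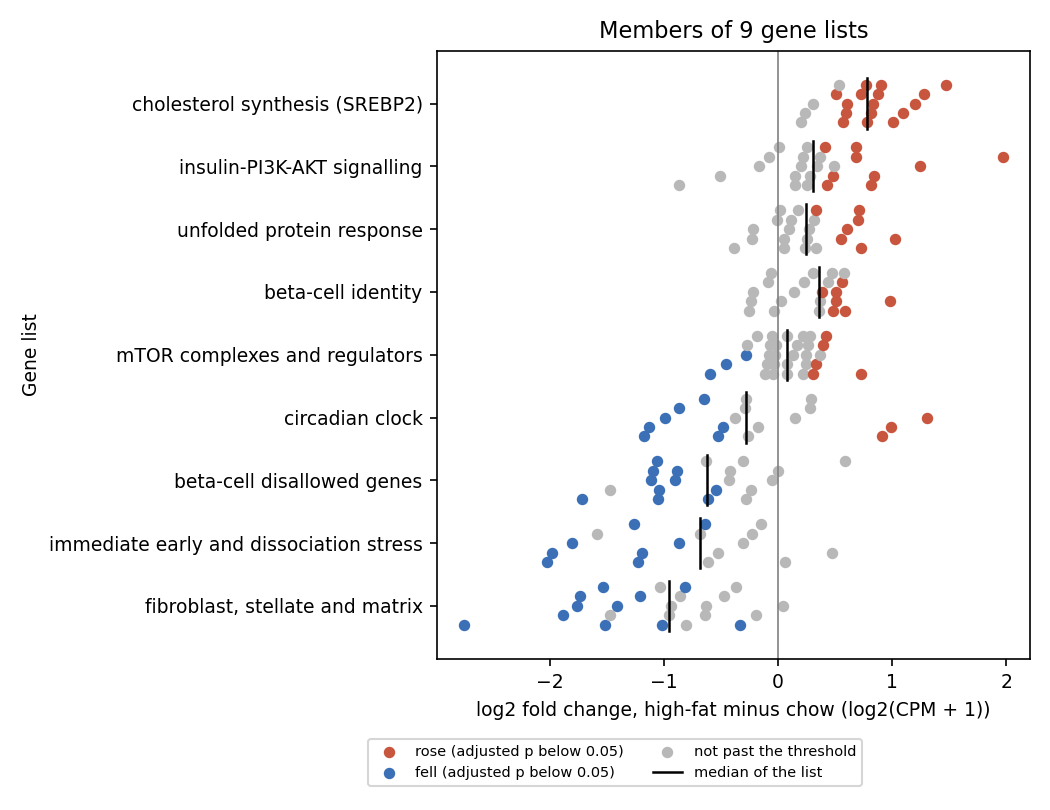
Log2 fold changes (high-fat diet minus chow, on the log2(CPM + 1) scale) of the tested members of 9 gene lists, 1 point per gene, with the median of each list as a black bar. In the cholesterol synthesis list 16 of 20 genes rose (6 with acinar and insulin genes out of the library size), and in the fibroblast list 11 of 23 fell (22). That scaling shifted all genes down, to a median of -0.34. It took the medians of the insulin signalling, unfolded protein response, beta-cell identity and mTOR lists below 0. Less the median of all genes, these 4 medians were then at 0.20, 0.13, 0.24 and -0.04.

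Sex-linked genes and the strain-variable gene Nnt were examined as a check of the samples. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were present in each of the 5 libraries (lowest value 16.8 CPM, for Kdm5d), and Xist lay between 0.18 and 1.13 CPM. Eif2s3y was at -0.35 ± 0.09 (adjusted p = 0.0309, limma). Nnt was at 18.6 and 23.1 CPM (adjusted p = 0.0785). Under the scaling without acinar and insulin genes, calls were gained by Ddx3y (0.0169, log2 -0.62), Kdm5d (0.00729, log2 -0.72) and Uty (0.0125, log2 -0.42) (limma adjusted p). Eif2s3y (0.0792) lost its call with the acinar score as a covariate, with adjusted p in brackets (limma for genes). Eif2s3y (0.598) did so after removal of length and GC trends in protein-coding genes. Eif2s3y (0.0611) did so with no filter. Eif2s3y (0.0552) did so with no trend in the variance prior. Nnt (0.0192) gained a call with all 6 columns. Eif2s3y lost its call without chow replicates 1 and 3 and high-fat replicates 1, 2 and 3 (limma adjusted p = 0.061, 0.0774, 0.094, 0.087 and 0.084). Ddx3y gained a call without chow replicate 3 (limma adjusted p = 0.0168).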

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

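The fits with all 6 columns, with a trimmed mean of M values, with other added constants, with no trend in the prior, on protein-coding genes only and with length and GC trends removed were chosen after the data were seen. Counts of 2524 higher and 1487 lower genes became 788 and 6932 with library sizes without acinar and insulin genes, 1080 and 573 with no filter (more genes tested), 1169 and 761 with the acinar covariate, 389 and 178 against a log2 fold change of 0.5 (a stricter hypothesis), and 4224 and 2828 with all 6 columns, where the averaged column narrows the chow spread. Against 2048 higher protein-coding genes with the deposited CPM, 1678 were higher among protein-coding genes without acinar and histone genes under median-ratio scaling, which changes 2 choices, and 1520 among protein-coding genes after removal of length and GC trends. Where no reason is given, the cause was not tested. Leaving out a replicate gave 1167 to 2969 higher and 682 to 1487 lower genes, and leaving out chow replicate 2 changed nothing, since the fit did not use it. A group left with 1 library was assumed to vary like the other.

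Lists called higher (4) and lower (6) ranged from 2 to 4 and 4 to 6 without 1 replicate, were 0 and 0 with an estimated correlation, and fry called 0 lower. The insulin share difference, 0.689 points, ranged from -1.37 to 2.75, and the acinar one, -13, from -21.5 to -4.6, without 1 replicate. Adjusted p of limma's list tests stand in brackets below. With median-ratio scaling, the ribosomal protein (0.0512) list was no longer past the threshold. Without acinar and insulin genes in the library size, the acinar (0.497), insulin signalling (0.0527) and unfolded protein response (0.332) lists were no longer past the threshold, and the alpha-cell (0.00343), dedifferentiation (0.0486), erythroid (0.00511) and oxidative phosphorylation (0.0167) lists passed it. With no filter, the alpha-cell (0.0289), erythroid (0.0483) and clock (0.013) lists passed it. With a filter at 1 CPM, the cell cycle (0.171) list was no longer past the threshold. With sample weights, the cell cycle (0.0534) list was no longer past the threshold. With the acinar covariate, the acinar (0.881, by construction), ribosomal protein (0.511) and cell cycle (0.173) lists were no longer past the threshold, and the alpha-cell (0.0172) and clock (0.0355) lists passed it. With all 6 columns, the ribosomal protein and cell cycle (0.0637) lists were no longer past the threshold. On protein-coding genes without acinar and histone genes, with median-ratio scaling, the ribosomal protein (0.0534) list was no longer past the threshold. On protein-coding genes after removal of length and GC trends, the ribosomal protein (0.0708) list was no longer past the threshold, and the clock (0.0342) list passed it. With an estimated correlation, the disallowed gene, acinar, fibroblast, endothelial, insulin signalling, cholesterol synthesis, unfolded protein response and immediate early (0.861), ribosomal protein (0.88) and cell cycle (0.862) lists were no longer past the threshold. With fry, the disallowed gene, fibroblast and immediate early (0.122), acinar and ribosomal protein (0.475), endothelial (0.198), insulin signalling (0.0717), unfolded protein response (0.109) and cell cycle (0.267) lists were no longer past the threshold, and the dedifferentiation (0.0314), glycolysis (0.0478) and autophagy (0.0127) lists passed it, and the delta-, PP- and epsilon-cell (0.0478) list took the other direction. Without 1 replicate, the lists that crossed the threshold were acinar (1.57e-08 to 0.143), alpha-cell (5.52e-05 to 0.652), beta-cell identity (0.0374 to 0.593), cell cycle (0.000211 to 0.25), clock (0.0473 to 0.0778), ribosomal protein (8.55e-05 to 0.841), erythroid (0.00763 to 0.237), secretory (0.0372 to 0.586) and unfolded protein response (0.00344 to 0.131), with the lowest and highest adjusted p.

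Of 115 named genes past the threshold, 50 kept their side of it in every alternative run in which they were tallied, and 72 in every omission of 1 library. Named genes were not tallied in the test against a set minimum fold change, so these counts do not cover it. With library sizes without acinar and insulin genes, genes called higher with the deposited CPM had a negative fold change, with adjusted p of limma in brackets, for Glp1r (0.591), Rraga (0.393), Elovl6 (0.817), Atp5o (0.936), Ppp1r15a (0.613), Hexa (0.959), Gabarapl1 (0.573) and Mtor (0.828), and Akt1 (0.0294), Foxo1 (0.0255) and Uty (0.0125), not called before, were called lower. No named gene past the threshold changed sign elsewhere. The count-based test planned as the main test was not run, since the values are not counts. The share of mitochondrially encoded genes was 0 in every setting. Values under 3 reads (0.0856 to 0.16 CPM by library) were not detectable at this depth.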

Other observations

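The genes and tests in this part were chosen after the values were seen, except the tests of small RNA genes, of length and GC content and of shared sequence in genes with large rises, and the count of splits, which were set before their results were seen. Relative to the median of the other acinar markers but amylase in each library, 6 of 33 acinar transcripts with values of their own were higher and 10 lower on the high-fat diet (limma, adjusted over these genes). Higher were the zymogen granule protein Sycn (1.23 ± 0.14, log2, SE), the bile salt-activated lipase Cel (0.51 ± 0.12), colipase Clps (0.48 ± 0.13), the protease Ctrl (0.58 ± 0.11) and the transcription factor Rbpjl (1.0 ± 0.20). Lower were the amylase genes Amy2a1 (-1.12 ± 0.09), Amy2a5 (-1.09 ± 0.11) and Amy2b (-0.98 ± 0.10), the granule membrane protein Gp2 (-1.18 ± 0.14), the trypsin inhibitor Spink1 (-0.93 ± 0.22) and the trypsinogen Try4 (-0.70 ± 0.11). Pnlip (0.06 ± 0.11) and Cpa1 (-0.16 ± 0.08) did not pass.

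The nuclear RNA Malat1 was at 347 and 643 CPM in chow replicates 1 and 3 and at 2068, 3036 and 2442 CPM in the high-fat replicates. Gm26917 was at 80.8 and 91.4 against 35343, 35469 and 40815 CPM. Gata3, a transcription factor, was at 28871 CPM in high-fat replicate 3 and between 2648 and 8298 CPM in the other 4 libraries.

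For the small structured non-coding RNAs that were nearly absent from chow, depth is argued against, since the smallest log2 fold change of the 5 RNAs was 8.45 and the deepest library had 1.86 times the reads of the shallowest. A candidate explanation is that the chow libraries were selected for polyadenylated RNA and the high-fat libraries were not. Other RNAs that mostly lack a poly(A) tail (histone, snRNA, snoRNA and scaRNA genes) had a median log2 fold change of 1.33, with 54 of 68 past the threshold and higher, against 0.05 for other protein-coding genes. The 18S ribosomal RNA entry, also without a poly(A) tail, lay the other way without passing the threshold (limma adjusted p = 0.0531). It was at 16771 and 14475 CPM in chow and 4231 ± 47.3 CPM (SD, n = 3) on the high-fat diet. Selection by itself does not predict this direction. Whether ribosomal RNA was removed from any library is not given, so the 18S entry does not decide for or against selection. Diet stays open and cannot be told apart from library type, as 0 of 2 chow libraries reached the lowest high-fat level of any of the 5 RNAs.

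The excess of amylase over the other acinar transcripts was smaller on the high-fat diet. Varying exocrine carry-over alone, which would move all acinar transcripts by 1 factor, is argued against. The summed amylase genes lay 5.14 and 4.93 log2 units above the median of the other acinar markers in chow and 4.04, 4.02 and 3.98 in the high-fat libraries, a difference of -1.02. Reads shared between amylase paralogs are also argued against, since the sum over the amylase genes held 93.4% of the difference of Amy2a5. Diet was not tested apart from library type, which cannot be told apart from it here, with 0 chow libraries of the high-fat type.

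Among protein-coding genes, 121 were past the threshold and more than 4-fold higher on the high-fat diet. These 121 held Pou4f1, Lhx2 and 14 histone genes, a class whose mRNAs mostly lack a poly(A) tail. Annotated small RNA genes lying wholly within them, miRNA genes not counted, are argued against. Of the 121 genes 6.61% held one, against 7.25% of the other tested protein-coding genes (Fisher's exact test, two-sided p = 1). Removal of the trends with length and GC content left 100% of them past the threshold and higher, with a median log2 fold change of 3.39 before and 3.24 after. Most of their 31-base words lay in another annotated gene in 10 of them (8.26%), against 4.66% of the others, and 8 of these 10 were histone genes. Near-identical annotated copies could therefore account for few of them. Reads from shorter shared stretches, or from sequence outside the annotated transcripts, were not tested. Diet and other differences between the library types stay open and cannot be told apart.

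The 10 splits of the 5 libraries into 2 and 3 are too few for a share under 0.05. The split by diet gave 4011 genes past the threshold, and was the 1 split with as many, and the highest of the other splits gave 0 genes.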
